A study of Synechocystis sp. PCC 6803 with 3 samples.

How the data were processed

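Photosystem II complexes of the cyanobacterium Synechocystis were purified through a His tag on the core antenna protein CP47, digested with trypsin and measured by liquid chromatography and mass spectrometry with the accurate mass and time tag approach, per the labels. The strain that carries the tag, HT3, was compared with 3 strains that carry the tag and lack PsbP, PsbQ or PsbV. Each strain was represented by 1 preparation. Per the file headers, the 9 columns of the abundance table are technical runs, 3 of the HT3 preparation and 2 of each mutant preparation.

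The values of the abundance table are peptide intensities in arbitrary units, which the authors deposited as raw abundances. A peptide not measured in a run is blank in the deposited table, and blanks made up 34.4% of its cells. The software, filters and scaling used by the authors to make these intensities are not given in the sources used here. The deposited list of tandem mass spectra holds a cross-correlation score (XCorr), a score difference (DeltaCn) and the precursor charge of each match. Its program and filters are not given in the sources used here, and its runs could not be assigned to strains.

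The table held 1242 entries of 1211 distinct peptides under 397 loci. Of the peptides, 23 stood under more than 1 locus, and such peptides occurred in 25 loci, among them the D1 loci, the D2 loci and the FtsH loci. Only 1 peptide was listed for 194 of the loci. Each run was scaled so that the median log2 level of the 39 peptides of the large core subunits (D1, D2, CP47 and CP43) measured in all 9 runs was equal. Values are therefore levels per photosystem II core, as that median gives it. Scaled log2 values were averaged over the runs of a preparation. The log2 ratio of a protein was the median over its peptides measured in both preparations, in proteins with at least 2 such peptides. A protein counted as higher or lower from a 2-fold difference on. The level of a protein was the sum of its scaled peptide abundances, averaged over runs. A protein with no peptide in 1 of the preparations has no ratio and is listed with its level alone.

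With 1 preparation per strain, no test between strains was possible, and no p-values were computed. The spread between runs is technical error only, and the spread between peptides of a protein is given where it matters. Peptide intensities are not counts, so no counting interval applies to them. For each protein list, the median log2 ratio was placed as a percentile among 10000 random lists of the same size, matched on level in 5 bins. That percentile describes these preparations and is no p-value. The lists were the large core subunits of photosystem II, its low-mass subunits, its extrinsic proteins, its assembly and repair factors, the slr0144-slr0152 gene cluster, the small CAB-like proteins, photosystem I, the phycobilisome, cytochrome b6f, ATP synthase, the NDH-1 complex, the ribosome, chaperones, carbon fixation and carboxysome, chlorophyll, haem and carotenoid synthesis, and periplasm and outer membrane. The slr0144-slr0152 cluster is known to have been singled out by the study on these samples, so its values are not independent evidence.

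The proteins named were set by a rule: PsbP, PsbQ and PsbV throughout, up to 6 proteins with the largest log2 ratio in each direction among those with at least 2 peptides measured in every run of both preparations, and every measured member of the core, low-mass, extrinsic, assembly and cluster lists. It further took up to 3 members of highest level from each other list, and up to 6 proteins with at least 2 peptides in 1 preparation and none in the other. Proteins named outside it are said to have been chosen after their values were seen. The scaling, the 2-fold size, the lists, this rule and the alternatives were chosen before the data were examined, with the exceptions that follow. A scaling by the median, over the same 39 peptides, of each peptide's difference from its own mean over the runs was chosen after seeing the data. So were the comparison of 6 settings side by side, the extrinsic list without the proteins deleted in the strains compared, and the XCorr minimum of 1.9, 2.2 and 3.7 for charges 1, 2 and 3 that served as the stricter score. The 6 settings were that scaling, the scaling described above, values as deposited, scaling to all peptides, scaling to CP47 alone, and peptides assigned to 1 protein alone.

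The other alternatives were summed peptide abundances, missing values set to the lowest value of the run, at least 1 or at least 3 peptides, the median over runs or the log2 of their mean, and leaving out each run in turn. Shares of tandem mass spectra are given with exact (Clopper-Pearson) 95% intervals, which cover counting error only. The overlap of the mutants' lists was set against independent lists and against 200 simulations with no effect and a shared HT3 preparation, with the spread between runs alone. After the data were seen, 200 more were made with the spread between peptides added for each mutant and 200 with it placed in HT3, all rescaled to the core. The procedure was tested on simulated data with these blanks and spreads. That was a single simulation for each mutant, with 15 changed proteins for each fold. There, 4-fold changes passed the 2-fold size in the right direction in 100% of proteins with the error of the PsbP deletion, 80% with that of the PsbQ deletion and 93.3% with that of the PsbV deletion. True 2-fold changes passed it in 66.7%, 26.7% and 46.7%. Unchanged proteins passed it in 1.82%, 12.1% and 12.9%. A list of 4 unchanged proteins had median log2 ratios of 0.22, 0.34 and 0.96 there, at percentiles 42.6, 71.7 and 83.3. A list of 4 proteins raised 4-fold had 2.08, 2.00 and 1.96, at percentiles 99.1, 99.5 and 98.2. The error of the scaling itself had an SD of 0.34, 0.14 and 0.23 on the log2 scale, against 0.098, 0.13 and 0.13 for the scaling by paired differences. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Gene coordinates were not used here.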

Results

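Peptide abundances were measured in affinity-purified photosystem II of the tagged strain HT3 and of its PsbP, PsbQ and PsbV deletion mutants, 1 preparation each, in 3 runs of HT3 and 2 of each mutant. No preparation was replicated, so the differences below are between single preparations and were not tested. In the HT3 runs 662 to 710 peptides of 202 to 229 loci were measured, with summed abundances of 2615 to 2915 (arbitrary units). The PsbP deletion runs held 794 and 806 peptides, the PsbQ deletion runs 849 and 898, and the PsbV deletion runs 830 and 909. Their summed abundances were 3360 and 3509, 3652 and 3874, and 3092 and 3366. Loci measured in any run numbered 244 in HT3, 283 in the PsbP deletion, 319 in the PsbQ deletion and 339 in the PsbV deletion. Set against HT3, 71, 98 and 109 loci were measured in the PsbP, PsbQ and PsbV deletion alone, and 32, 23 and 14 in HT3 alone. A protein measured in a mutant alone was thus common. The HT3 runs had the fewest peptides and the lowest summed abundances, so a protein blank there was not shown to be absent. The SD of a peptide's log2 abundance between runs was 0.41 in HT3 and 0.76, 0.78 and 0.69 in the mutants.

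The deleted proteins were looked at first. PsbV (sll0258), cytochrome c550 of the lumenal side, had a summed level of 192 to 220 in the HT3 runs and of 0.41 and 0.58 in the PsbV deletion runs. The median ratio of its 3 peptides measured in both preparations was 197-fold lower (log2 ratio -7.62). PsbQ (sll1638), a lumenal lipoprotein, had a level of 114 to 159 in HT3. In the PsbQ deletion no peptide of it was measured in run 1, and 1 of 9 in run 2, with a level of 0.44 (log2 ratio -5.89 by that peptide). PsbP (sll1418), another lumenal lipoprotein, was listed with 1 peptide. That peptide was listed in no HT3 run, in run 1 of the preparation labelled PsbP deletion at 0.46, in run 2 of the PsbQ deletion at 1.94 and in run 2 of the PsbV deletion at 0.22. The abundances thus neither bear out nor contradict the label of the PsbP deletion.

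**Figure D1:**
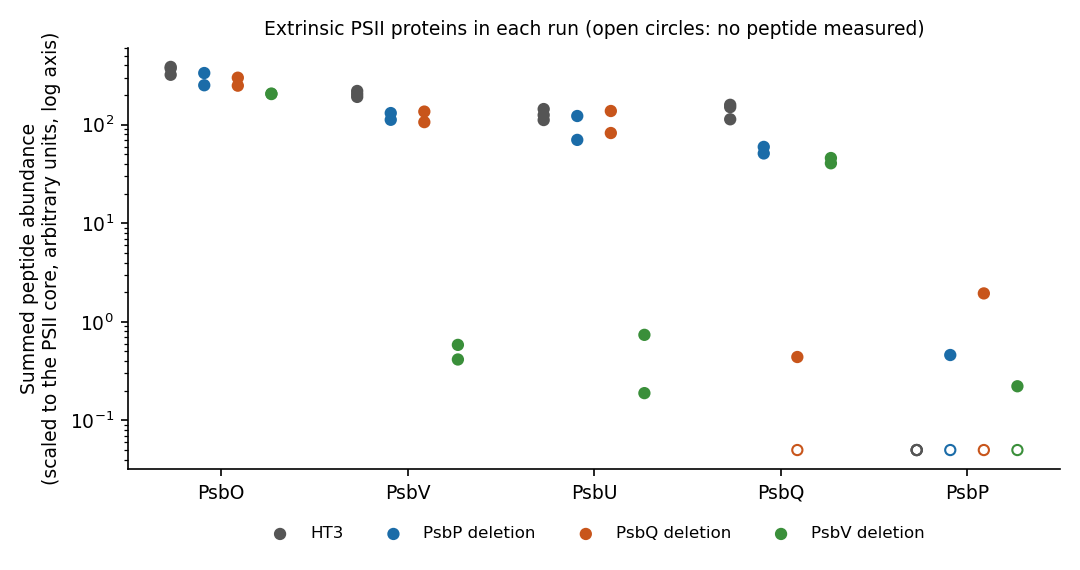
Summed peptide abundance of the 5 extrinsic photosystem II proteins in each run, scaled to the photosystem II core (arbitrary units, log axis). Each point is a run, coloured by preparation, and open circles mark runs with no peptide of the protein, drawn at the bottom of the axis. PsbV and PsbU lay under 1 in both PsbV deletion runs, against 112 to 220 in the HT3 runs.

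The comparison of the PsbP deletion with HT3 asked which proteins came with the complex in a different amount in the strain labelled as lacking PsbP. Proteins of the slr0144-slr0152 gene cluster, whose members the files mostly annotate as hypothetical, were higher in the PsbP deletion. All 4 members with at least 2 peptides were past 2-fold, with a median of 5.94-fold (log2 ratio 2.57) at percentile 99.79 of random lists. slr0144 was 6.98-fold higher, slr0147 6.30-fold, slr0151 5.59-fold (8 peptides, SD 0.80 between their log2 ratios) and slr0149 3.63-fold. slr0146 was 3.67-fold higher by 1 peptide, and slr0145 was measured in the mutant alone, at a level of 3.53. This cluster was chosen by the study on these samples and is not independent evidence. Outside the cluster, ssr0692, of unknown function, was 4.36-fold higher, the carboxysome shell protein CcmK (sll1028) 3.20-fold and OpcA (slr1734), of the oxidative pentose phosphate pathway, 2.89-fold. Of these, ssr0692 alone stayed past 2-fold under all 6 settings. Fructose-bisphosphate aldolase (sll0018), chosen after its values were seen, was 20.1-fold higher by 2 peptides.

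Phycocyanin and ATP synthase subunits were lower in the PsbP deletion. Of the phycobilisome list, the light-harvesting antenna, 8 members were in the table, and in each mutant only the 2 phycocyanin subunits had a ratio by at least 2 peptides. Their median log2 ratio here was -1.97 (percentile 1.58), with CpcB (sll1577) 6.36-fold and CpcA (sll1578) 2.43-fold lower. The linker CpcG1 (slr2051) was measured in HT3 alone, at 1.05. The 2 ATP synthase subunits with at least 2 peptides had a median of -2.15 (percentile 0.74), with AtpA (sll1326) 6.68-fold and AtpB (slr1329) 2.96-fold lower. AtpD (sll1325) was 9.03-fold lower by 1 peptide. The nitrate transport protein NrtC (sll1452) was 7.32-fold lower, slr0172, of unknown function, 5.28-fold, the glycolytic enzyme enolase (slr0752) 5.22-fold by 10 peptides, and the Calvin cycle bisphosphatase FbpI (slr2094) 4.75-fold. The periplasmic list was at -1.46 (percentile 5.56), with its 3 members that have a ratio, the phosphate-binding protein (sll0680), NrtA (sll1450) and FutA1 (slr1295), 2.24-fold, 2.75-fold and 3.44-fold lower.

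The scaling to the photosystem II core made the median level of its peptides equal, which does not set the median ratio of the core list to 0. That ratio was -0.40 here, and -1.03 with CP47 alone as the scale. The CP47 scale likewise made the median level of 12 CP47 peptides equal, which does not set the ratio of CP47 to 0. The ratios below are to be read beside the ratio of the core list. The extrinsic list had a median of -0.81 (percentile 7.29). That percentile was 1.15 with at least 3 peptides, 12.1 without run 1 of the mutant and 19.9 with summed abundances. PsbQ, at -1.59, was 3.00-fold lower, and PsbV, at -0.96, was 1.94-fold lower, while PsbU and PsbO had log2 ratios of -0.67 and -0.56. The core list was at -0.40 with none of its 7 loci past 2-fold, and CP47 (slr0906), CP43 (sll0851), D2 (sll0849 and slr0927, shared peptides) and D1 (slr1311 and sll1867, shared peptides) at -0.27, -0.40, -0.06 and -0.47. The D1 locus slr1181 was at -0.69. Among the low-mass subunits (median -0.19), PsbH was at -0.27 and PsbE at -0.10, and by 1 peptide each PsbL was at -0.26 and PsbY 2.91-fold higher. In the assembly list (median -0.38, 9 members), Ycf48 (slr2034), an early assembly factor, was 2.27-fold lower. Psb27 (slr1645) was at -0.34, Psb28 (sll1398) at 0.22, Psb29 (sll1414) at -0.85, Psb32 (sll1390) at 0.02 and the FtsH proteases (slr0228, slr1604, slr1390 and sll1463), which share peptides, at -0.49 to -0.16. RubA (slr2033) was at 0.51 by 1 peptide, and Psb28-2 (slr1739) was measured in the mutant alone, at 0.61. The core, low-mass and assembly medians and the PsbO, PsbU and Psb27 ratios took the other sign in at least 1 of the 6 settings. PsbQ and Ycf48 did not stay past 2-fold under all of them.

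The other lists with a ratio for at least 2 members were inside the middle 95% of random lists, but carbon fixation moved from percentile 27.7 to 78.5 with at least 1 peptide and to 99.2 with missing values set to the lowest of the run. Photosystem I was at -0.09 with PsaA (slr1834), PsaC (ssl0563) and PsaD (slr0737) at -0.09, 0.65 and -0.40, NDH-1 at -0.28, carbon fixation at -0.51 and chlorophyll, haem and carotenoid synthesis at -0.04. These medians, too, took both signs over the 6 settings. The single chaperone with a ratio, GroEL (slr2076), was at 0.25. The large subunit of Rubisco (slr0009) had a ratio of -0.51 by its 2 shared peptides but a summed level of 22.6 against 4.69, since most of its 13 peptides in the mutant were not measured in HT3. Ribosomal proteins gave no ratio by at least 2 peptides, and their list was at percentile 7.42 with at least 1 peptide and 0.15 with missing values set to the lowest of the run. L6 (sll1810), L17 (sll1819) and L2 (sll1802) were measured in HT3 alone, at 1.35, 0.35 and 0.28. In the mutant alone, polyphosphate kinase (sll0290), the small heat shock protein Hsp17 (sll1514), a Na+/H+ antiporter (slr1727), the zinc exporter ZiaA (slr0798) and sll0703 were measured at 11.4, 3.81, 2.28, 2.27 and 1.31.

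In all, 12 of 115 proteins were higher and 31 lower, 10 and 18 of them in every one of the 6 pairs of runs. Between runs of 1 preparation, 1 to 5 of 109 to 115 proteins in HT3 and 12 to 15 of 121 to 135 in the mutants were past 2-fold. The split depended on the setting: 28 higher and 13 lower as deposited, 21 and 19 with paired core differences, 16 and 29 with all peptides, 6 and 55 with CP47 alone, and 27 and 12 with unshared peptides. Under all 6 settings 6 were higher and 12 lower, and the median log2 ratio of all proteins moved between -0.97 and 0.34. The phycobilisome percentile was 6.78 without run 2 of the mutant, 2.54 without run 2 of HT3, 2.51 with summed abundances, 4.66 with at least 1 peptide and 4.52 with missing values set to the lowest of the run. That of ATP synthase was 8.27 without run 1 of the mutant and 18.2 with summed abundances.

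The comparison of the PsbQ deletion with HT3 asked the same question for PsbQ. The slr0144-slr0152 proteins were again higher, all 4 members with at least 2 peptides past 2-fold with a median of 7.76-fold (log2 ratio 2.96, percentile 99.74; not independent evidence). slr0144 was 8.50-fold higher, slr0151 8.45-fold, slr0147 7.13-fold and slr0149 4.66-fold. slr0146 was 4.33-fold higher by 1 peptide, and slr0145 was measured in the mutant alone, at 6.41. ssr0692 was 8.88-fold higher (SD 0.20 between 2 peptides), and sll1106, of unknown function, 4.12-fold. Psb28 (sll1398), an assembly factor bound to CP47, was 4.67-fold higher by 3 peptides with an SD of 1.58, and its relative Psb28-2 (slr1739) was measured in the mutant alone, at 2.43. Aldolase (sll0018), 31.3-fold higher, and the pyridoxal phosphate enzyme PdxJ (slr1779), 4.99-fold higher, were chosen after their values were seen.

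The phycobilisome and ATP synthase lists were lower again, at -2.18 (percentile 0.77) and -2.19 (percentile 0.29). CpcB was 8.16-fold and CpcA 2.53-fold lower, while CpcG1 was 3.28-fold higher by 1 peptide. AtpA was 5.44-fold lower as a median over 3 peptides whose log2 ratios had an SD of 2.48, and its log2 ratio was 0.87 with summed abundances, the opposite direction. AtpB was 3.84-fold lower (SD 2.25), and AtpD was measured in HT3 alone, at 1.05. The NDH-1 list, of respiratory and cyclic electron transport, was at -1.08 (percentile 7.98), with NdhI (sll0520) 3.15-fold lower and NdhK (slr1280) and NdhH (slr0261) at -0.87 and -0.64. slr0442, of unknown function, was 3.33-fold lower, and deoxyxylulose phosphate synthase (sll1945), of isoprenoid synthesis, 3.00-fold. Glutamate synthase GltB (sll1502) and L2 were measured in HT3 alone, at 1.19 and 0.28.

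Of the remaining extrinsic proteins with a ratio, PsbV was at -0.87, PsbU at -0.80 and PsbO at -0.47, none past 2-fold (list percentile 4.45). That percentile was 39.4 without run 1 of the mutant, 40.6 with summed abundances and 0.67 with missing values set to the lowest of the run. The core list was at -0.32 with none of 7 loci past 2-fold: CP47 at 0.09, CP43 at -0.32, D2 at 0.18, D1 at -0.49 and slr1181 at -0.60. The low-mass list was at 0.06, with PsbH at -0.59, PsbE at 0.70, and by 1 peptide PsbL at 0.04 and PsbY 5.13-fold higher. The assembly list was at 0.17. Psb27, which binds CP43 during assembly, was 2.17-fold higher, Ycf48 was at -0.04, Psb29 at -0.34, Psb32 at 0.53, the FtsH proteases at -0.85 to 0.19 and RubA 3.21-fold higher by 1 peptide. All 3 of these medians, and the PsbO ratio, took both signs over the 6 settings, while the PsbV, PsbU and Psb27 ratios kept theirs. Psb27 did not stay past 2-fold under all of these settings.

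The remaining lists were inside the middle 95% of random lists, which did not hold in every alternative. Carbon fixation moved from percentile 9.16 to 94.2 without run 1 of the mutant, 91.7 with at least 3 peptides, 98.6 with missing values set to the lowest of the run, 2.30 with summed abundances and 2.10 with unshared peptides. The ribosome moved from 22.1 to 1.36 with at least 1 peptide and 1.39 with missing values set to the lowest, and NDH-1 to 0.72 without run 1 of the mutant. Photosystem I was at -0.06, with PsaA, PsaC and PsaD at -0.15, 0.94 and -0.30. Carbon fixation was at -0.37, with CcmK (sll1029) 3.03-fold higher, Gap2 (sll1342) 2.21-fold lower and Rubisco (slr0009) at -0.37, with a summed level of 24.3 against 4.69. Chlorophyll, haem and carotenoid synthesis was at 0.90, with Ycf59 (sll1214), an enzyme of chlorophyll synthesis, 3.18-fold higher and HemB (sll1994) at 0.13. ChlP (sll1091) was 7.28-fold lower by 1 peptide. The periplasmic list was at 0.74, with the phosphate-binding protein at 0.74, NrtA at 0.91 and FutA1 at -0.97. These 4 medians changed sign in at least 1 of the 6 settings. The 2 ribosomal proteins with a ratio had a median of -0.85, L6 among them at -1.10, and GroEL was at 0.11. In the mutant alone, Hsp17 reached 22.0, polyphosphate kinase 11.7, chorismate synthase (sll1747) 2.38 and ZiaA 1.78.

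In all, 24 of 118 proteins were higher and 21 lower, 16 and 8 of them in every pair of runs. The split was 43 and 10 as deposited, 29 and 16 with paired core differences, 19 and 31 with all peptides and 9 and 58 with CP47 alone. Under all 6 settings 9 were higher and 10 lower, and the median of all proteins moved between -0.92 and 0.63. The phycobilisome percentile was 3.28 without run 1 of the mutant, 4.52 with at least 1 peptide and 11.0 with missing values set to the lowest of the run, and that of ATP synthase was 43.3 with summed abundances.

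The comparison of the PsbV deletion with HT3 asked the question for PsbV. Of the 3 remaining extrinsic proteins with a ratio, PsbU (sll1194), which binds next to PsbV, was 25.1-fold lower by 2 peptides and PsbQ 2.91-fold lower by 6. PsbO (sll0427), the manganese-stabilizing protein, was at -0.95 by 17 peptides, short of 2-fold. The list median was -1.54 (percentile 0.59) without the deleted PsbV and -3.10 (percentile 0.04) with it. PsbU and PsbQ stayed past 2-fold under all 6 settings, and PsbO kept its sign. The PsbU ratio ranged from -6.12 to -0.29 over the pairs of runs, and its level was 0.19 and 0.74 in the mutant runs against 112 to 144 in HT3.

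The slr0144-slr0152 proteins were higher here as well, with all 4 members with at least 2 peptides past 2-fold and a median of 8.90-fold (log2 ratio 3.15, percentile 99.95; not independent evidence). slr0151 was 11.1-fold higher, slr0144 8.92-fold, slr0147 8.88-fold, slr0149 5.94-fold and slr0146, by 1 peptide, 6.37-fold. slr0145 was measured in the mutant alone, at 6.05. Ribosomal proteins were higher, all 6 with a ratio past 2-fold, with a median of 3.78-fold (log2 ratio 1.92, percentile 99.63). L6 was 3.97-fold higher, L3 (sll1799) 3.45-fold and L12 (sll1746), by 1 peptide, 5.03-fold. The DNA-binding protein HU (sll1712) was 6.38-fold higher by 5 peptides, a chemotaxis receptor (sll1294) 4.64-fold and a magnesium transporter (slr1216) 4.29-fold. The alpha subunit of RNA polymerase (sll1818) was measured in the mutant alone, at 2.64. Glycogen synthase GlgA (sll0945), 11.5-fold higher, the photosystem I assembly protein Ycf37 (slr0171), 4.25-fold higher, and aldolase (sll0018), 32.7-fold higher, were chosen after their values were seen.

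**Figure D2:**
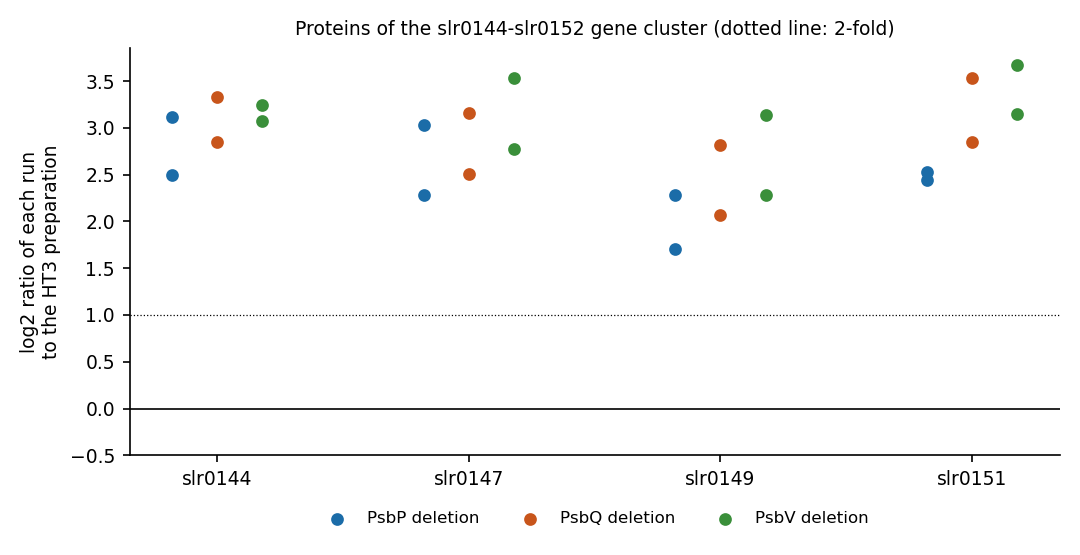
Log2 ratio of each mutant run to the HT3 preparation for the 4 proteins of the slr0144-slr0152 cluster with at least 2 peptides in both preparations, coloured by mutant. Each point is a run, the solid line marks no difference and the dotted line a 2-fold difference. Every point lies above the dotted line.

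The phycobilisome list was at -1.83 (percentile 0.22), but at 0.043 (percentile 26.1) with missing values set to the lowest of the run. CpcA was 4.43-fold and CpcB 2.85-fold lower, while CpcG1 was 2.58-fold higher by 1 peptide. NrtC was 3.52-fold lower, the isoprenoid enzyme GcpE (slr2136) 3.45-fold, AtpA 2.88-fold and AtpD, by 1 peptide, 3.78-fold, while AtpB was at -0.02. The ATP synthase list was at -0.78 (percentile 2.88). NDH-1 was at 1.25 (percentile 97.17), with NdhK 2.72-fold and NdhH 2.29-fold higher and NdhI at 0.51, but its median was 0.55 in 1 of the 6 settings, with 0 members higher in all of them. Carbon fixation was at -0.74 (percentile 3.23), with Gap2 2.14-fold lower, CcmK (sll1029) at 0.60 and Rubisco at -0.74. The periplasmic list was at -0.82 (percentile 2.80), with the phosphate-binding protein 2.09-fold lower, NrtA at -0.57 and FutA1, by 1 peptide, 3.15-fold lower. Chlorophyll, haem and carotenoid synthesis was at 1.22, with Ycf59 3.60-fold higher and HemB at 0.58, and ChlP was measured in HT3 alone, at 0.68. Photosystem I was at 0.58, with PsaA, PsaC and PsaD at 0.03, 1.04 and 0.71, and its sign was not kept over the 6 settings. Over all alternatives the percentiles reached down to 79.0 for NDH-1 and ran from 0.27 to 20.3 for ATP synthase, 1.45 to 24.8 for carbon fixation and 1.13 to 6.09 for the periplasmic list. GroEL was at 0.89, and ClpC (sll0020) was 4.21-fold higher by 1 peptide. In the mutant alone, polyphosphate kinase, Hsp17, sll0602 and the antiporter slr1727 were measured at 4.07, 3.60, 3.04 and 2.25. In HT3 alone, an aminopeptidase (sll1343) and RfbA (sll0207) were measured at 0.31 and 0.12.

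The core list was at -0.27 with none of 7 loci past 2-fold: CP47 at 0.16, CP43 at -0.41, D2 at -0.27, D1 at -0.18 and slr1181 at -0.33. The low-mass list was at -0.34, with PsbE at -0.68 and, by 1 peptide each, PsbL at 0.60 and PsbY at 0.97, while PsbH differed by less than 0.01. The assembly list was at 0.51. Ycf48 was 2.24-fold higher, Psb27 was at 0.85, Psb29 at 0.73, Psb32 at -0.90, Psb28 at -0.67, the FtsH proteases at 0.44 to 0.52 and RubA 3.78-fold higher by 1 peptide. Psb28-2 was not measured in either preparation. The core and assembly medians took both signs over the 6 settings, and the Ycf48, Psb27, Psb29, Psb32 and Psb28 ratios kept theirs. Ycf48 did not stay past 2-fold under all of these settings. In all, 30 of 122 proteins were higher and 14 lower, 18 and 9 of them in every pair of runs. The split was 47 and 12 as deposited, 43 and 12 with paired core differences, 20 and 30 with all peptides, 17 and 32 with CP47 alone and 40 and 11 with unshared peptides. Under all 6 settings 17 were higher and 12 lower, and the median of all proteins moved between -0.37 and 0.70.

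**Figure D3:**
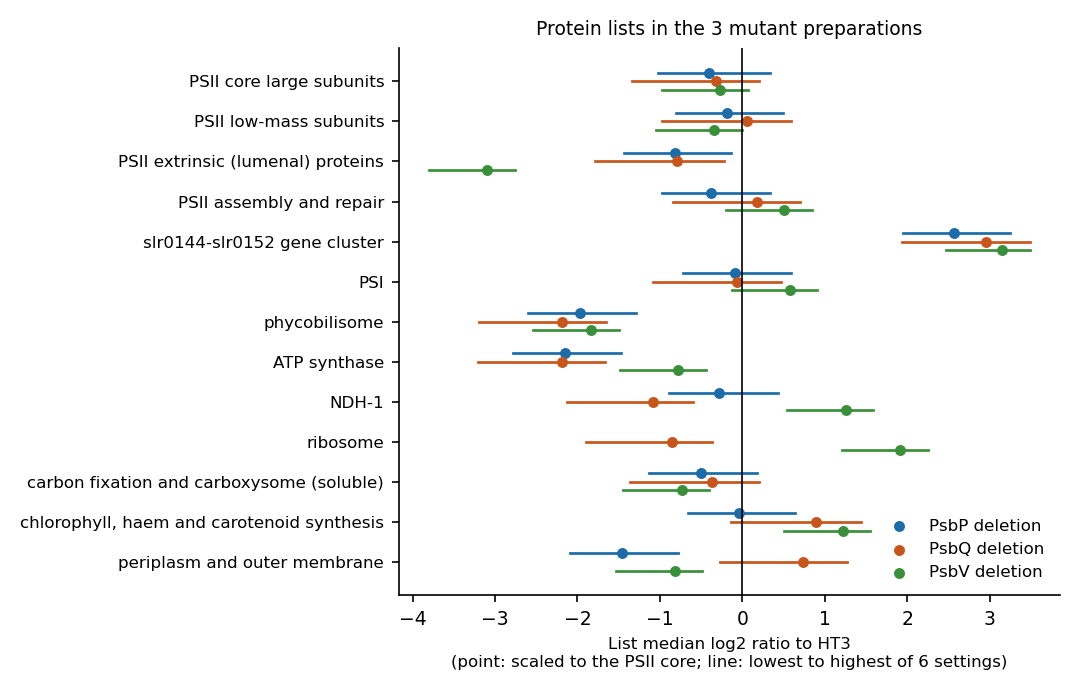
Median log2 ratio to HT3 of each protein list with at least 2 members that have a ratio, in the 3 mutant preparations. Points are scaled to the photosystem II core, and lines run from the lowest to the highest of the 6 settings. The cluster lies above 1.9 and the phycobilisome below -1.2 in all 3 mutants, and the ribosome lies above 1 in the PsbV deletion.

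Because the mutants share the HT3 preparation, differences among them were taken from direct ratios. Against the PsbQ deletion, the PsbP deletion had 4 of 141 proteins higher and 27 lower. PilA1 (sll1694), the major pilin, was at -3.18, Hsp17 at -2.64, slr0172 at -2.68, NrtA at -1.85 and Ycf59 at -1.80, and NDH-1 was at 0.88 (percentile 99.89), with NdhI at 1.20. Against the PsbP deletion, the PsbV deletion had 42 of 135 proteins higher and 7 lower, with GlgA at 3.46, Ycf59 at 2.48, HU at 2.04 and Ycf48 at 1.98. There, Rubisco (slr0009) was at -2.37, ssr0692 at -2.07 and carbon fixation at -0.81 (percentile 0.18). The extrinsic list was at -0.57 (percentile 6.54) without PsbV, and at -2.85 (percentile 0.47) with it, and its member PsbU was at -5.13. Against the PsbQ deletion, the PsbV deletion had 32 of 144 higher and 20 lower. All 4 NDH-1 members with a ratio were higher there (median 1.98, percentile 99.39), L4 (sll1800) was at 2.94 and L6 at 3.09 (ribosome percentile 99.90). PsbU and PsbO, the extrinsic proteins deleted in neither strain that had a ratio, were at -4.91 and -0.49 (list percentile 0.74). Psb28 was at -2.61, Psb32 at -1.55, ssr0692 at -3.17 and carbon fixation at -1.01 (percentile 2.09), a median that reached 0.089 in 1 of the 6 settings. Apart from PsbO, the proteins in this paragraph were picked after their values were seen, from those past 2-fold under all 6 settings.

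The slr0144-slr0152 medians were -0.67 between the PsbP and PsbQ deletions, 0.69 between the PsbV and PsbP deletions and 0.07 between the PsbV and PsbQ deletions, with a sign that depended on the setting. The splits did too. For the PsbP against the PsbQ deletion they were 7 higher and 20 lower as deposited, 13 and 13 with all peptides, 11 and 16 with CP47 alone, 7 and 19 with paired core differences and 21 and 10 with unshared peptides. For the PsbV against the PsbP deletion they were 26 and 16, 18 and 22, 37 and 9, 33 and 11, and 17 and 17, in the same order. For the PsbV against the PsbQ deletion they were 27 and 24, 26 and 26, 47 and 14, 32 and 20, and 39 and 14. Under all 6 settings the counts were 4 and 10, 18 and 7, and 24 and 14 for the 3 pairs of mutants.

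Of 110 proteins with a ratio in all 3 mutants, 6 were higher and 9 lower in each. The higher ones were aldolase (sll0018), sll1130 and the 4 cluster proteins. The lower ones were CpcA, CpcB, AtpA, NrtC, the Calvin cycle enzymes Gap2 and phosphoribulokinase (sll1525), pyruvate kinase (sll0587), an oxidoreductase (slr1208) and GcpE. sll1130, phosphoribulokinase, pyruvate kinase and slr1208 were chosen after their values were seen. The PsbP and PsbQ deletions shared 8 higher and 17 lower proteins, against 2.44 and 5.04 for independent lists. The PsbP and PsbV deletions shared 8 and 11, against 2.59 and 3.78, and the PsbQ and PsbV deletions 9 and 9, against 5.43 and 2.37. Simulations with no effect and a shared HT3 preparation gave means of 0 to 0.01 shared proteins from the spread between runs alone. With the spread between peptides of a protein added and the runs rescaled, they gave 0.34 to 1.94 when that spread was drawn for each mutant. When it lay in HT3, they gave 3.78 to 4.11, and the observed numbers were reached in 5 to 29 of 200 simulations. Part of the sharing may thus come from the shared HT3 preparation.

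The tandem mass spectra listed the proteins identified over all their runs together, which could not be assigned to strains. The shares below are of these spectra and do not give the composition of a preparation. In all, there were 4673 spectra of 1097 peptides, with at least 2 peptides for 189 loci. The core list took 1205 spectra (25.8%, interval 24.5 to 27.1), the extrinsic proteins 689 (14.7%, 13.7 to 15.8), and the assembly and repair list 474 (10.1%, 9.29 to 11.0). The slr0144-slr0152 cluster took 126 spectra (2.70%, 2.25 to 3.20) of 30 peptides in 6 loci. Carbon fixation took 138 spectra, the periplasmic list 78, the low-mass subunits 70, photosystem I 65, chaperones 63, the phycobilisome 59 and the ribosome 56. NDH-1 took 37, ATP synthase 34, chlorophyll, haem and carotenoid synthesis 29 and cytochrome b6f 1. For cytochrome b6f, PetA (sll1317) was in the abundance table with 1 peptide, at -0.97 in the PsbQ and -0.03 in the PsbV deletion, and in HT3 but not in the PsbP deletion. No small CAB-like protein was in the abundance table, and they took 0 of 4673 spectra (upper limit 0.079%).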

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

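The tests of the ribosomal proteins below were all chosen only after the result was seen.

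Some proteins stood on opposite sides of HT3 in different mutants, and these differences were not tested. PilA1 (sll1694), the major pilin, had a log2 ratio of -1.97 in the PsbP deletion (-2.60 to -1.29 over the 6 settings). It was at 1.21 in the PsbQ deletion, a ratio that did not stay past 2-fold under all 6 settings. The direct ratio of the PsbP to the PsbQ deletion was -3.18 (-3.18 to -2.49). Ycf48 (slr2034), an early assembly factor of photosystem II, was at -1.18 in the PsbP deletion (-1.80 to -0.50 over the 6 settings) and 1.16 in the PsbV deletion (0.46 to 1.49), with a direct ratio of 1.98 (1.23 to 1.98). The ribosomal protein L6 (sll1810) was at -1.10 in the PsbQ deletion (-2.12 to -0.57) and 1.99 in the PsbV deletion (1.28 to 2.32), with a direct ratio of 3.09 (2.84 to 3.40). In the tandem mass spectra, 73 spectra of 30 peptides belonged to peptides outside the abundance table, a signal that the comparisons do not use.

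L6 belongs to a wider pattern: 20 of 21 ribosomal loci were measured in the PsbV deletion, with a summed level of 35.6, against 12 loci and 7.24 in HT3, 6 and 0.91 in the PsbP deletion and 14 and 4.07 in the PsbQ deletion. The tables argue against the scaling as the whole cause, since the ribosome median stayed at 1.21 or more over the 6 settings. They also argue against a carry-over of soluble proteins of every kind, since the carbon fixation and carboxysome list was at -0.74, with its highest member at 0.95, below the lowest ribosomal protein with a ratio, at 1.63. Nucleic acid that came with this preparation, together with its bound proteins, may be a source: the nucleic-acid-binding proteins with a ratio had a median of 1.17, but they were only 3, HU at 2.67, polynucleotide phosphorylase (sll1043) at 1.17 and elongation factor Tu (sll1099) at -0.21. That set was taken by annotation words: DNA binding, RNA polymerase, ribonucleotide nucleotidyltransferase or elongation factor. Proteins annotated in other words, such as the LexA repressor (sll1626), were not in it. Without a ratio, the RNA polymerase subunits RpoB (sll1787) and RpoA (sll1818) had levels of 1.46 and 2.64 here against 0 in HT3 and at most 0.62 in the other mutants, but elongation factors G (slr1463) and Ts (sll1261) had 0 here against 0.40 and 0.066 in HT3, and the phosphorylase had 24.5 here against 29.7 and 25.7 in those. That source, an effect of the missing PsbV and a difference of this single preparation stay open.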

How the results depend on the processing

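The scaling by paired core differences, the extrinsic list without the deleted proteins and the values of the stricter score were chosen only after the data were seen, and the other alternatives before. Of the alternative values of the 18 main results, 191 stayed within the run-to-run SD, or within 1.5 times for counts, and 76 moved further. The 16 counts have no direction of their own, but the larger side of the split between higher and lower turned in all 3 mutants against HT3, in the PsbP deletion as deposited and in the PsbQ and PsbV deletions with all peptides or CP47 alone, among others. Of 26, 25 and 30 proteins past 2-fold among those named in the PsbP, PsbQ and PsbV deletions, 13, 13 and 21 stayed past it in every alternative that gave a value. As deposited, the PsbP deletion had 28 proteins higher and 13 lower, the PsbQ deletion 43 and 10, and the PsbV deletion 47 higher. There, the PsbP against the PsbQ deletion had 7 higher, and the PsbV against the PsbP deletion 26 and 16. Scaled to CP47 alone, the counts against HT3 were 6 and 55, 9 and 58, and 17 and 32, those of the PsbP against the PsbQ deletion 11 and 16, and the deleted PsbQ and PsbV were at -6.95 and -8.33. Scaled to all peptides, PsbQ and PsbV were at -6.37 and -8.19, 30 proteins were lower in the PsbV deletion, and the PsbP against the PsbQ and the PsbV against the PsbP deletion had 13 and 13, and 18 and 22. With paired core differences, the PsbP deletion had 21 and 19, the PsbP against the PsbQ deletion 7 higher and the PsbV against the PsbP deletion 11 lower. A scaling moves all proteins of a run alike, so these counts follow from its construction. With unshared peptides alone, the PsbP deletion had 27 and 12, the PsbP against the PsbQ deletion 21 and 10, and the PsbV against the PsbP deletion 17 and 17. This setting also takes the shared peptides out of the scaling, so it changes the scaling too. The median of all proteins in the PsbP deletion moved from -0.34 to 0.34. The part due to the scaling and the part due to the peptides left were not separated.

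With missing values set to the lowest of the run, which gives a ratio to 203 proteins, the counts against HT3 were 30 and 54, 51 and 40, and 68 and 23. Those among the mutants were 12 and 50 (PsbP against PsbQ), 78 and 18 (PsbV against PsbP) and 53 and 31 (PsbV against PsbQ). There, 5 lists lay outside the middle 95% in the PsbQ deletion, PsbQ was at -7.53, and the phycobilisome median in the PsbV deletion turned to 0.043, and the cause was not tested. With at least 1 peptide, which takes in more proteins, the counts were 33 and 60, 52 and 35, 67 and 24, 11 and 53, 84 and 14, and 75 and 40, in the same order. With at least 3, which takes in fewer, the counts against HT3 were 7 and 17, 14 and 8, and 13 and 6, those of the PsbV against the PsbQ deletion 14 and 12, and 24 were higher in the PsbV than in the PsbP deletion. With summed abundances, 1 list lay outside the middle 95% in the PsbP deletion, and in the PsbQ deletion AtpA (sll1326) turned to 0.87 and the ATP synthase median to 0.23. The cause was not tested. Without the deleted PsbV, the extrinsic median in the PsbV deletion was -1.54 instead of -3.10, since PsbV itself is its lowest member.

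Leaving out 1 run at a time, the deleted PsbV lay between -8.15 and -7.33, the lists outside the middle 95% in the PsbV deletion numbered 4 to 7, the latter without run 2 of HT3, and the proteins lower in the PsbV than in the PsbP deletion 5 to 11, the latter without run 1 of the PsbP deletion. The proteins identified by tandem mass spectrometry numbered 189, 335 with at least 1 peptide, 109 with peptides in at least 2 spectra, which is a narrower criterion, and 188 with the stricter score. No paired analysis was possible because each strain is 1 preparation. The ratio of PsbQ in the PsbQ deletion rests on 1 peptide, against the minimum of 2 used elsewhere, and has no value with at least 3 peptides or without run 2 of that preparation. Precision is limited by the single preparation, by the choice of scaling and by the spread between peptides of 1 protein, with a median SD of 0.73, 1.04 and 0.74 in the 3 mutants.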

Other observations

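The tests of the slr0144-slr0152 cluster below were chosen only after the result was seen, and the test within proteins was chosen before.

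Some proteins outside the fixed lists, chosen after their values were seen, differed under all 6 settings. In the PsbP deletion, a protein of sulfolipid synthesis (slr0384) had a log2 ratio of -2.77, proline oxidase (sll1561) -2.20, enoyl reductase (slr1051), of fatty acid synthesis, -1.71 and aspartyl-tRNA synthetase (slr1720) -1.68. slr0384 was at -0.18 in the PsbQ deletion, and the direct ratio of the PsbP to the PsbQ deletion was -2.60. In the PsbQ deletion, a sulfolipid biosynthesis protein (slr1020) was at -1.56. Aldolase (sll0018) was 20.1-fold, 31.3-fold and 32.7-fold higher in the PsbP, PsbQ and PsbV deletions.

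The slr0144-slr0152 proteins were higher in all 3 mutant preparations. The tables argue against the scaling as the whole cause, since the lowest cluster median over the mutants and the 6 settings was 1.94. They also argue against a different extent of trypsin digestion in HT3 that all peptides of a cleavage class share. The class medians of the other peptides lay between -0.64 and 0.45. With each of the 19 cluster peptides set against the other peptides of its class, the lowest median over the mutants was 2.56. Only 3 of the 19 held a missed cleavage, so this comparison rests mainly on fully cleaved peptides. This comparison could not detect a digestion difference of the cluster proteins alone. A difference of the single HT3 preparation in culture, purification or measurement cannot be told apart from a rise in every deletion, since the cluster differed by at most 0.69 among the mutants and HT3 was prepared once. A hypothesis is that these proteins may stay with complexes that lack a lumenal protein, which was not tested. A replicate HT3 preparation would show only whether the single HT3 preparation differed, and would not by itself test that hypothesis.

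Peptides of 1 protein gave different ratios to HT3. A different extent of digestion in HT3 would give peptides with a missed cleavage site a shared offset in all 3 mutants, relative to fully cleaved peptides of the same protein. That offset was -0.063 in the PsbV deletion (interval -0.30 to 0.026, 58 proteins), which argues against such a difference of HT3 as the whole cause. It was -0.40 in the PsbP deletion (interval -0.78 to -0.15, 54 proteins) and -0.64 in the PsbQ deletion (interval -1.001 to -0.34, 52 proteins). A more complete digestion of those preparations may account for part of the spread between peptides there, and no biological explanation was tested.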
